A study of Mus musculus with 24 samples.

How the data were processed

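Lung tissue was taken from healthy C57BL/6 mice at postnatal days 1, 4, 7, 14 and 42, per the labels, with 5 biological replicates per age and 4 at day 42. The series title calls the lungs fetal, whereas each sample is described as postnatal. The source name of 1 day 14 sample gives replicate 3 where its title and description give 4, and the title was followed. Total RNA was isolated with miRNeasy kits, and labelled with Cy3 for 1-colour arrays on slides of 8, per the labels' protocols. Each array held 59305 non-control spots for 55681 probes, and each replicate was taken as 1 animal, which the labels do not state.

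The processed signal of each spot, an intensity with background subtracted and spatial trend removed, came from Feature Extraction 10.7.3.1, per the file headers. The submitters' processing notes give version 10.7.1.1. Median spot and local background intensity, and 0 or 1 flags for spots well above background, saturated or not uniform, are other columns of the same scans, per the file headers. The table of log2 values that the authors deposited covers 52095 probes and gives each array as log2 of the processed signal plus a smooth shift of its own, by a method not stated.

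The comparisons, tests, filters, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined. Log2 of the processed signal was used, minus the 75th percentile of each array. Control spots and spots marked as not uniform were left out, spots of a probe were averaged, and 138 probes with no usable spot on some array were dropped. Probes were named through a RefSeq gene table of GRCm38.p6, used for names alone. It matched 26041 of 26695 probes with a RefSeq transcript accession, and 26056 probes carried 1 of 19752 gene symbols. The other 29625 probes had no gene name, 16194 of them because they are named by a genome region. Each gene was represented by the probe with the highest mean over the 24 arrays. A gene was tested when that probe was well above background on at least 4 arrays, which left 15898 genes. On all arrays 0 spots were saturated.

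Ages were compared with limma 3.58.1 in R 4.3.3, with 1 mean per age and all 24 arrays in 1 fit (prior degrees of freedom 3.04). P-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. A moderated F-test covered any ages. Genes highest or lowest at days 4, 7 or 14 had to differ by a log2 of 1 or more from both day 1 and day 42, with adjusted p under 0.05 in both contrasts. Their number with no effect was simulated 20 times, and compared with the overlap of independent lists and with a fit that gives each contrast its own arrays of the shared age.

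The 36 gene lists were written from textbook knowledge, covering lung and immune cell types, matrix, signalling, cell division, metabolism, clock, stress, sex-linked genes and neighbouring tissues. They hold 624 symbols, of which 605 were on the array, and lung itself expresses many genes of the lists for other tissues. Each list was tested against all other genes with camera at a preset correlation of 0.01, adjusted over 180 tests. The test was repeated with the correlation estimated for each list, and with fry, which asks whether the genes of a list move one way on balance. With the estimated correlation 4, 1, 4, 2 and 5 lists passed from day 1 to 4, 4 to 7, 7 to 14, 14 to 42 and 1 to 42, against 16, 6, 22, 19 and 21 with the preset one. For every list called, the median, mean and test had the same sign.

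The rule for named genes took the 6 largest rises and falls per comparison among genes past the test whose groups did not overlap and that were measured on both sides. It added up to 4 members past the test for each list called, the 2 largest changes from day 1 to day 42 for lists called nowhere, and 5 genes for each kind of intermediate age. The measured-on-both-sides condition was added after the data were examined. Of the 201 genes so named, 123 appear in the text, a selection made for length after their values were seen, and some are not reported here. A gene that was well above background on 0 arrays of a group is given as at least a number of times higher or lower. That bound sets the other group's mean against the lowest normalized signal of a well-above-background probe on each array.

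The scripts were tested on simulated data with 15898 genes, of which 100 changed by 2-fold and 100 by 4-fold. In the same order of comparisons, 43%, 34%, 42%, 36% and 32% of the 2-fold genes were recovered, and 83%, 84%, 87%, 78% and 85% of the 4-fold genes. Of unchanged genes 3, 4, 7, 8 and 8 were called, and 0 changed genes had the wrong direction. Of 200 genes raised at day 7 by a log2 of 4, 99.5% were found.

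Alternatives changed 1 choice at a time, except the first: normexp background with offset 50, quantile normalization, median scaling, the authors' table, no filter or a filter on all 24 arrays, the mean of a gene's probes, each probe tested, a slide or replicate block, Xist level as a covariate, array weights, a variance trend, only the ages compared, and leaving out each array. Normexp was run on median spot signals (mean ones, as planned, were not used here), so the signal statistic, detrending and background changed together. Results without 5 arrays, without 6 arrays, without sex-linked genes, and with Xist as a covariate without the 5 arrays were added after seeing the data. Probe sequences, transcript lengths and gene positions were not used here.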

Results

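Whole lungs of healthy C57BL/6 mice were profiled at postnatal days 1, 4, 7 and 14 (n = 5 each) and 42 (n = 4). Each of the 24 samples was hybridized to 1 single-colour (Cy3) array, which reads the level of each transcript as spot brightness. Every age was present on each of 3 slides of 8 arrays. Between 50.4% and 79.7% of the spots on an array lay well above background, and the 75th percentile of the processed signal ran from 476.1 to 1652.7 intensity units. Each age was compared with the one before it, and day 42 with day 1. A value after a gene is its log2 difference ± SE from the limma fit, unless another quantity is named, and the p of a gene list is that of camera, adjusted over 36 lists and 5 comparisons. A fold in a count is the fitted one, and medians within slides are given in the order of slides 1, 2 and 3.

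Of 15898 genes tested, 4995 (31.4%) differed between any of the 5 ages. The first principal component (49.9% of the variance) set 5 arrays apart from the other 19: day 1 replicates 4 and 5, day 4 replicates 1 and 3, and day 42 replicate 4. Neither Xist, the X-inactivation transcript, nor the Y-linked Ddx3y was well above background on these 5 arrays, while at least 1 of them was on each of the other 19. The 5 arrays also had the lowest 75th percentiles (at most 979.3, others at least 995.5) and shares of spots well above background (at most 56.0%, others at least 57.0%). The second component (27.8%) set day 42 and 4 of 5 day 14 arrays apart from those of days 1, 4 and 7. Day 14 replicate 5 lay between the day 7 and the other day 14 arrays. The counts of genes per comparison are therefore also given without the 5 arrays and without all 6, and those of list members without the 5 where that moved them by over 1.5 times, choices made after the data were seen. Genes that differed between any ages numbered 8488 without the 5 arrays and 8996 without the 6.

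**Figure D1:**
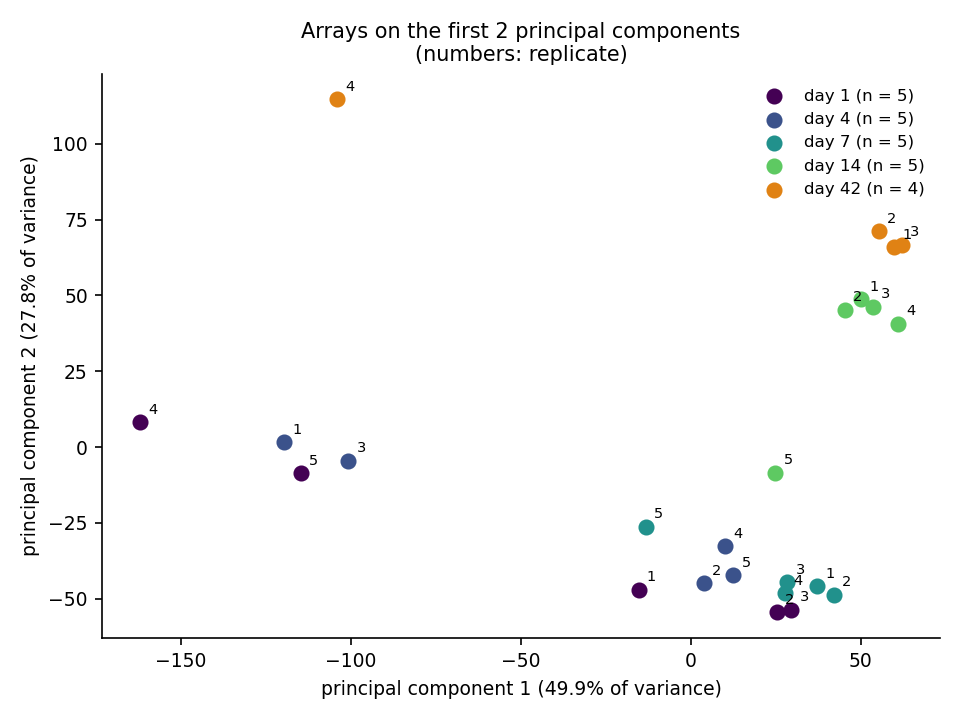
Arrays on the first 2 principal components of the normalized log2 levels (unitless scores), one point per array, coloured by age and numbered by replicate, with 49.9% and 27.8% of the variance on the axes. The 5 arrays that stand apart lie at -100.7 or lower on the first component.

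From day 1 to day 4 few single genes passed the test. Higher at day 4 were Cd209a (1.5 ± 0.26), a lectin receptor of dendritic cells, Scube2 (1.19 ± 0.18), a secreted aid of Hedgehog release, and Bmp2 (0.93 ± 0.15), a bone morphogenetic protein. Also higher were Prkcq (0.93 ± 0.15), a protein kinase C of T cells, and Vsnl1 (0.77 ± 0.14), a calcium sensor, while Ptges3l (-0.81 ± 0.15) fell. These 6 genes had adjusted p = 0.0102 to 0.0451 by limma (n = 5 and 5). The cell cycle list, genes of DNA replication and mitosis, fell as a group (median -0.65 (-0.74 with a slide block and -0.76, -0.72 and -0.34 within slides)). It had adjusted p = 1.15e-25, and p = 0.0378 with estimated correlation, with 0 of its 42 genes past the test over all genes and 0 lower adjusted over the list alone. Neutrophil and granulocyte precursor genes fell too (median -0.49, adjusted p = 1.35e-07, and p = 0.0393 with estimated correlation), with 2 lower adjusted over the list alone. Imprinted growth genes, which are expressed from 1 parental copy, fell (median -0.28, adjusted p = 0.000399, and p = 0.0323 with estimated correlation), with 2 lower adjusted over the list alone. Lipofibroblast genes, markers of lipid-storing interstitial cells, rose (median 0.26, adjusted p = 0.00413, and p = 0.0499 with estimated correlation).

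In the same interval 12 further lists passed only with the preset correlation, and 0 list members passed over all genes. T and NK cell genes rose (median 0.60, adjusted p = 1.08e-10, and p = 0.197 with estimated correlation), with 3 higher adjusted over the list alone. Interferon-stimulated genes rose (median 0.45, adjusted p = 8.55e-08, and p = 0.0805 with estimated correlation), with 4 higher adjusted over the list alone. MHC class II presentation genes, which display antigen to T cells, rose (median 0.51, adjusted p = 0.00699, and p = 0.567 with estimated correlation). The circadian clock list rose (median 0.27, adjusted p = 0.00052, and p = 0.0904 with estimated correlation), with 1 higher adjusted over the list alone. Rises were also called for alveolar type 1 genes of the flat gas-exchange epithelium (median 0.20, adjusted p = 0.0156, and p = 0.367 with estimated correlation). Endothelial genes (median 0.18, adjusted p = 0.0132, and p = 0.66 with estimated correlation) and pericyte genes of capillary support cells (median 0.26, adjusted p = 0.0491, and p = 0.143 with estimated correlation) rose in the same test, the pericyte list with 1 gene higher adjusted over the list alone. So did adipocyte genes (median 1.12, adjusted p = 0.00234, and p = 0.404 with estimated correlation) and immediate early and heat shock genes (median 0.10, adjusted p = 0.0287, and p = 0.721 with estimated correlation). Falls were called for mast cell genes (median -0.58, adjusted p = 0.000384, and p = 0.0798 with estimated correlation), cholesterol synthesis genes (median -0.22, adjusted p = 0.0258, and p = 0.503 with estimated correlation) and cardiac muscle genes (median -0.86, adjusted p = 0.00028, and p = 0.494 with estimated correlation). For cardiac muscle genes, markers of a neighbouring tissue, day 1 replicate 2 alone carried the call: without it adjusted p = 0.479 and the direction turned.

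Over all genes, 9 passed the limma test between day 1 and day 4 (6 higher, 3 lower), 5 of them by at least 2-fold, and 814 had an unadjusted p under 0.05. There were 12 without the 5 arrays, of which 2 were among the 9, and 254 without the 6. With the compared ages alone 0 passed, which ends all 9 calls, while array weights gave 489 and 99 passed in the authors' table. Quantile normalization gave 32 (25 higher) and median scaling 4 (2 higher). Leaving out 1 array moved the count by over 1.5 times in 9 cases: day 1 replicates 2 and 5 and day 4 replicates 2 and 5 (5 each), day 4 replicates 1, 3 and 4 (4 each), day 42 replicate 4 (17) and day 14 replicate 5 (44). With a slide block 7 genes passed, and all 9 kept their direction within each slide. Of the 16 lists called, 15 kept their call with the block, while pericyte genes had adjusted p = 0.0672. Medians within single slides ran against the call for alveolar type 1 (-0.0078 on slide 1), endothelial (-0.02 on slide 2), adipocyte (-0.43 on slide 2), immediate early and heat shock (-0.20 on slide 2), mast cell (0.04 on slide 3) and cholesterol synthesis genes (0.14 on slide 3). Immediate early and heat shock genes failed without any 1 of day 1 replicates 1, 2 and 3 and day 4 replicates 1 and 3 (adjusted p = 0.1 to 0.316), endothelial genes without day 1 replicates 2 and 3 or day 4 replicates 1 and 3 (0.0787 to 0.26), and MHC class II genes without day 1 replicates 2 and 3 or day 4 replicate 1 (0.0729 to 0.336). Cholesterol synthesis genes failed without day 1 replicates 3 and 5 or day 4 replicates 1, 2 and 4 (0.0564 to 0.152), alveolar type 1 genes without day 1 replicate 2 (0.148) and adipocyte genes without day 4 replicate 4 (0.189). Pericyte genes failed without any 1 of day 1 replicates 1, 3, 4 and 5, the 5 day 4 arrays, day 7 replicates 3 and 4, day 14 replicates 1, 3 and 5, and day 42 replicates 1 and 2 (0.0501 to 0.146). Without the 5 arrays immediate early and heat shock genes had adjusted p = 0.383, and the medians of cardiac muscle, adipocyte and cholesterol synthesis genes were -1.85, 1.84 and -0.12. With the normexp background those of T and NK cell, interferon-stimulated and pericyte genes were 0.33, 0.24 and 0.17.

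Between day 4 and day 7 the only gene to pass was Pde4b (-1.16 ± 0.14), a cyclic AMP phosphodiesterase, which was lower at day 7 (adjusted p = 0.00068, limma, n = 5 and 5). Cell cycle genes were lower again as a group (median -0.65 (-0.65 with a slide block and -0.48, -0.72 and -0.76 within slides)), with adjusted p = 0.00103, and p = 0.559 with estimated correlation. The sex-linked list was higher at day 7, median 3.46 (3.46 with a slide block and 3.97, 0.69 and 4.33 within slides), with adjusted p = 0.000227, and p = 0.0323 with estimated correlation, and 3 of its 4 genes were higher adjusted over the list alone. Ddx3y was well above background and Xist was not on each of the 5 day 7 arrays. The labels do not give the animals' sex. Arrays with Xist well above background numbered 2, 2, 0, 3 and 3 at days 1, 4, 7, 14 and 42. Random regroupings of the arrays of both ages called a median of 8 lists, against 6 here, so chance was not excluded. Alveolar type 2 and surfactant genes of the surfactant-making epithelium were called lower (median -0.48, adjusted p = 0.022, and p = 0.664 with estimated correlation), and B cell genes higher (median 0.10, adjusted p = 0.0177, and p = 0.485 with estimated correlation). Cholesterol synthesis genes fell (median -0.46, adjusted p = 0.0227, and p = 0.494 with estimated correlation), as did immediate early and heat shock genes (median -0.46, adjusted p = 0.0441, and p = 0.735 with estimated correlation), the latter with 3 lower adjusted over the list alone. Without the 5 arrays and in the authors' table the median of all genes was -0.06 and -0.01, in place of -0.27, and those of cell cycle, alveolar type 2, cholesterol synthesis and immediate early genes were -0.39, -0.14, -0.24 and -0.14, and -0.35, -0.07, -0.25 and -0.16 in turn. The 4 lists had adjusted p = 2.85e-07, 0.0245, 0.000112 and 0.451 without the 5 arrays. After quantile normalization the medians of cell cycle, alveolar type 2 and immediate early genes were -0.42, -0.16 and -0.24. The B cell median was 0.0018 with median scaling, 0.02 with the normexp background, 0.05 after quantile normalization and 0.24 in the authors' table, and the sex-linked one 1.97 with the normexp background. Day 4 replicates 1 and 3, among the 5, held alveolar type 2 means of 4.83 and 4.62, against at most 4.14 on the other arrays of both ages. The median of all genes was -0.37 with median scaling and -0.13 after quantile normalization, so list shifts are read against it.

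By limma 1529 genes had an unadjusted p under 0.05. Past the test were 8 without the 5 arrays, Pde4b among them, and 31 without the 6 arrays. The call ended with median scaling and with the compared ages alone (0 genes each), while array weights gave 5160 genes and 20 passed in the authors' table. The Xist level as a covariate gave 9016. Xist was also not well above background on the 5 arrays, so this covariate does not adjust for sex alone. The count was 4 without day 1 replicate 2, 6 without day 1 replicate 4, 2 without day 1 replicate 5, 14 without day 4 replicate 2, 13 without day 14 replicate 5, 3 without day 42 replicate 3 and 6 without day 42 replicate 4. With a slide block 1 gene passed, and Pde4b was lower at day 7 within each slide. All 6 lists kept their call with the block, and the B cell median ran against the call within slide 2 (-0.03). The cholesterol synthesis call ended without day 4 replicate 5 (adjusted p = 0.0779) or day 7 replicate 3 (0.0535). That of immediate early and heat shock genes ended without any 1 of day 1 replicates 2, 3, 4 and 5, day 4 replicates 1, 3 and 4, day 7 replicates 2 and 3, and day 42 replicate 4 (0.0503 to 0.079).

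**Figure D2:**
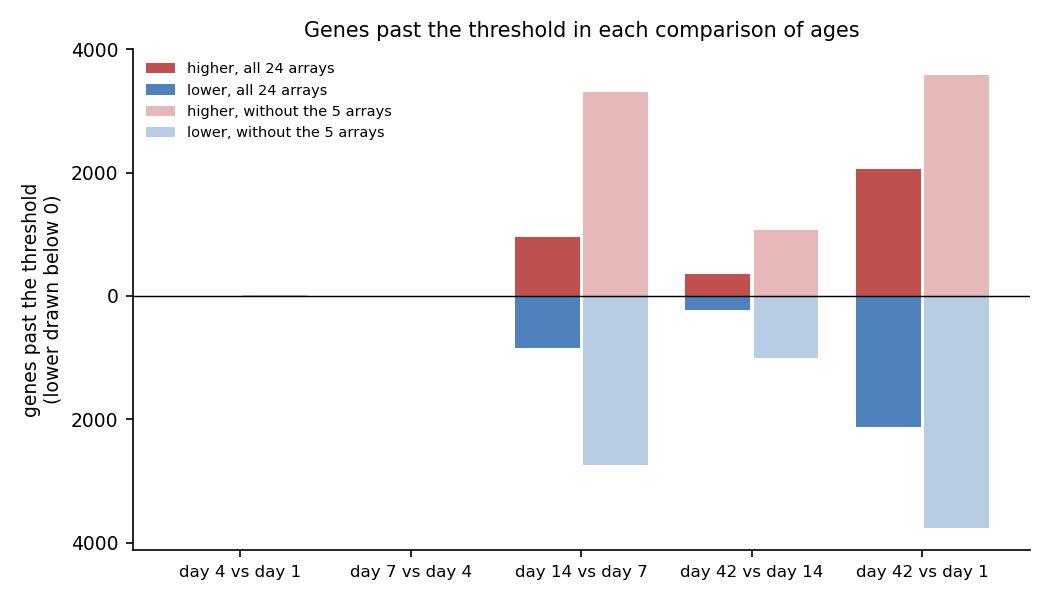
Genes past the threshold (adjusted p under 0.05 by limma) in each of the 5 comparisons, higher genes above 0 and lower genes below, for all 24 arrays (dark bars) and without the 5 arrays that stand apart (pale bars). The day 14 and day 7 comparison had 1796 genes with all arrays and 6048 without the 5.

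Of the steps between neighbouring ages, that from day 7 to day 14 had the most genes past the test, except with the Xist level as a covariate (2602, against 9016 from day 4 to day 7). Without the 5 arrays that exception was gone. Higher at day 14 were Serpina3n (5.11 ± 0.63), an inhibitor of serine proteases, Inmt (4.98 ± 0.54), an enzyme that methylates tryptamine, and Ms4a4d (4.96 ± 0.60), a membrane protein. Slc13a4 (4.70 ± 0.66), a sulfate transporter, Chil4 (4.50 ± 0.56), a chitinase-like protein, and Cfd (4.82 ± 1.28), the complement protease adipsin, rose as well. Lower were Prss35 (-5.32 ± 0.66), Dlk1 (-5.21 ± 0.74), an imprinted growth regulator, Lrrc15 (-5.01 ± 0.58), Prokr2 (-4.90 ± 0.71), a receptor for prokineticins, Shisa3 (-4.71 ± 0.56) and Phactr3 (-4.59 ± 0.42). These 12 genes had adjusted p = 1.51e-06 to 0.0144 (limma, n = 5 and 5). Several were near background on one side: at day 14 Prokr2, Shisa3 and Phactr3 were well above it on 1 of 5 arrays and Prss35 on 2 of 5, and at day 7 Serpina3n was on 3 of 5 and Ms4a4d on 2 of 5.

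Lists of proliferation and growth genes were called lower at day 14. Of 42 cell cycle genes 33 fell and 9 did not pass (1 higher and 41 lower adjusted over the list alone, 1 higher and 41 lower without the 5 arrays), adjusted p = 3.7e-34 and p = 0.0276 with estimated correlation. Aurkb (-3.15 ± 0.39), a kinase of chromosome segregation, and Cdk1 (-2.86 ± 0.38), the kinase of mitotic entry, were among them. Another probe of Cdk1 passed in the other direction, and Aurkb was well above background on 1 of 5 day 14 arrays. The list median was -1.75 (-1.72 with a slide block and -2.20, -2.07 and -1.20 within slides). Of 18 imprinted growth genes 7 fell and 11 did not pass (12 lower adjusted over the list alone, 12 without the 5 arrays), adjusted p = 1.17e-08 and p = 0.000862 with estimated correlation. Besides Dlk1 these included Mest (-2.54 ± 0.29), and the median was -0.90. Of 25 lung morphogen signalling genes 8 fell and 17 did not pass (11 lower adjusted over the list alone, 14 without the 5 arrays), adjusted p = 2.43e-07 and p = 0.193 with estimated correlation. Etv4 (-3.35 ± 0.52), a transcription factor of FGF signalling, and Shh (-1.49 ± 0.22), the Hedgehog ligand, were lower.

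Matrix, contractile and mast cell lists were called lower with the preset correlation only. Of 18 elastic fibre genes 1 rose, 5 fell and 12 did not pass (1 higher and 6 lower adjusted over the list alone, 4 higher and 12 lower without the 5 arrays), adjusted p = 0.00166 and p = 0.54 with estimated correlation. Fbn2 (-3.24 ± 0.41), a fibrillin of developing tissue, and Loxl2 (-1.72 ± 0.30), a crosslinking enzyme, fell, while Efemp1 (1.1 ± 0.16), a fibulin, rose. Of 22 fibrillar collagen and stromal matrix genes 1 rose, 5 fell and 16 did not pass (1 higher and 6 lower adjusted over the list alone, 3 higher and 10 lower without the 5 arrays), adjusted p = 0.0188 and p = 0.452 with estimated correlation. Tnc (-3.64 ± 0.49) and Vcan (-3.28 ± 0.44), a glycoprotein and a proteoglycan of provisional matrix, had the largest falls in that list. Of 19 smooth muscle and myofibroblast genes 2 rose, 7 fell and 10 did not pass (2 higher and 7 lower adjusted over the list alone, 2 higher and 11 lower without the 5 arrays), adjusted p = 0.00105 and p = 0.212 with estimated correlation. These included Tgfbi (-2.84 ± 0.46), an adhesion protein induced by TGF-beta, and Wnt5a (-1.72 ± 0.28), a secreted signal. Of 8 mast cell genes 3 fell and 5 did not pass (1 higher and 4 lower adjusted over the list alone, 1 higher and 4 lower without the 5 arrays), adjusted p = 0.00897 and p = 0.201 with estimated correlation. The mast cell proteases Mcpt4 (-2.76 ± 0.51) and Cma1 (-1.97 ± 0.37) fell.

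Epithelial and protective lists were called higher with the preset correlation only. Random regroupings of the arrays of both ages called a median of 16 lists that way, against 22 here. Of 19 alveolar type 1 genes 3 rose and 16 did not pass (3 higher adjusted over the list alone, 13 without the 5 arrays), adjusted p = 0.00263 and p = 0.242 with estimated correlation. Cyp2b10 (3.19 ± 0.46), a cytochrome P450, and Hopx (0.95 ± 0.21), a homeodomain protein of type 1 cells, rose. Of 22 alveolar type 2 and surfactant genes 2 rose and 20 did not pass (2 higher adjusted over the list alone, 11 without the 5 arrays), adjusted p = 0.00991 and p = 0.597 with estimated correlation. Sftpa1 (1.14 ± 0.36), surfactant protein A, was 1 of them. Of 18 ciliated airway genes 2 rose and 16 did not pass (2 higher adjusted over the list alone, 11 without the 5 arrays), adjusted p = 0.000359 and p = 0.257 with estimated correlation. Cdhr3 (0.87 ± 0.22), a cadherin-related protein of ciliated cells, was 1 of these. Of 18 club and secretory airway genes 4 rose, 1 fell and 13 did not pass (12 higher and 1 lower adjusted over the list alone, 11 higher and 1 lower without the 5 arrays), adjusted p = 8.21e-06 and p = 0.242 with estimated correlation. Aldh1a1 (1.76 ± 0.24) and Gsta3 (1.73 ± 0.28), enzymes that handle aldehydes and electrophiles, rose, while Upk3a (-1.90 ± 0.42), a uroplakin of a club cell subset, fell. Of 22 xenobiotic and antioxidant genes 9 rose and 13 did not pass (10 higher adjusted over the list alone, 16 higher and 1 lower without the 5 arrays), adjusted p = 1.28e-08 and p = 0.0904 with estimated correlation. Cyp1a1 (4.63 ± 0.80), the aryl hydrocarbon receptor target, and Gpx3 (3.29 ± 0.47), a secreted peroxidase, rose, with Cyp1a1 well above background on 2 of 5 day 7 arrays and 4 of 5 day 14 arrays.

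Besides the mast cell list, 6 immune lists were called, all higher at day 14 and 2 of them also with an estimated correlation, while neutrophil genes were not (adjusted p = 0.528). Of 22 interferon-stimulated genes 13 rose and 9 did not pass (19 higher adjusted over the list alone, 20 without the 5 arrays), adjusted p = 5.87e-11 and p = 0.0378 with estimated correlation. Ifit3 (1.98 ± 0.25) and Ifit1 (1.73 ± 0.42), which bind viral RNA, rose, and the list median was 1.06. Of 16 alveolar macrophage genes 4 rose and 12 did not pass (11 higher adjusted over the list alone, 13 without the 5 arrays), adjusted p = 8.66e-08 and p = 0.0323 with estimated correlation. Chil3 (4.03 ± 0.34), a chitinase-like protein, and Ear2 (0.90 ± 0.17), a ribonuclease, rose, with a list median of 0.77. Of 14 B cell genes 8 rose and 6 did not pass (11 higher adjusted over the list alone), adjusted p = 6.8e-08 and p = 0.0784 with estimated correlation. Pax5 (1.71 ± 0.32), the B lineage transcription factor, and H2-Ob (1.62 ± 0.28) rose, though Pax5 was well above background on 2 of 5 day 7 arrays. Of 23 T and NK cell genes 7 rose and 16 did not pass (18 higher adjusted over the list alone, 22 without the 5 arrays), adjusted p = 6.75e-09 and p = 0.242 with estimated correlation. Eomes (1.44 ± 0.32), a transcription factor of cytotoxic cells well above background on 2 of 5 day 7 arrays, was higher. Of 10 MHC class II presentation genes 4 rose and 6 did not pass (10 higher adjusted over the list alone, 10 without the 5 arrays), adjusted p = 1.89e-05 and p = 0.33 with estimated correlation. H2-Ab1 (1.22 ± 0.39), a class II beta chain, and Ctss (0.69 ± 0.17), a protease that processes the invariant chain, rose. Of 16 type 2 immune response genes 4 rose and 12 did not pass (6 higher adjusted over the list alone, 9 without the 5 arrays), adjusted p = 0.000344 and p = 0.14 with estimated correlation. Next to Chil4, Ccl17 (1.74 ± 0.36), a T cell chemokine, and Il4 (1.09 ± 0.23), the cytokine, were higher, with Il4 well above background on 3 of 5 day 7 arrays.

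Clock, stress and other tissue lists were called higher with the preset correlation. Of 18 circadian clock genes 8 rose, 2 fell and 8 did not pass (10 higher and 3 lower adjusted over the list alone), adjusted p = 0.00589 and p = 0.193 with estimated correlation. Nr1d1 (1.98 ± 0.36) and Dbp (1.97 ± 0.41), of the clock loop and its output, rose. Of 17 immediate early and heat shock genes 4 rose and 13 did not pass (6 higher adjusted over the list alone, 9 without the 5 arrays), adjusted p = 8.92e-05 and p = 0.452 with estimated correlation. Hspa1a (2.09 ± 0.55), a heat shock chaperone, and Atf3 (1.40 ± 0.36), a stress-induced transcription factor, rose. The labels do not give the time of day at which tissue was taken. Of 9 adipocyte genes, markers of fat that can adhere to dissected lung 3 rose and 6 did not pass (3 higher adjusted over the list alone), adjusted p = 0.0365 and p = 0.575 with estimated correlation. Cfd and Retn (2.49 ± 0.75), the adipokine resistin, were 2 of these. Of 9 mesothelial genes of the lung surface 1 rose and 8 did not pass (1 higher adjusted over the list alone, 2 without the 5 arrays), adjusted p = 0.0315 and p = 0.494 with estimated correlation. The 1 gene was Upk1b (0.83 ± 0.21), a uroplakin.

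By limma 1796 genes passed between day 7 and day 14 (952 higher, 844 lower), 1174 of them by at least 2-fold. Without the 5 arrays 6048 passed, including all 1796, and without the 6 arrays 6995 did. None of the 5 arrays was of day 7 or 14, so leaving them out could not change the differences or their direction. It changed only the estimated spread, for genes and for lists. The share of genes that were higher was 53% and fell to 31.5% with median scaling, which put the median of all genes at -0.17 in place of 0.03. With a slide block 1705 genes passed, and 99.9% of the 1796 kept their direction within each slide. All 22 lists kept their call with the block and the sign of their median within every slide. Calls were lost without the 5 arrays for fibrillar collagen and stromal matrix (adjusted p = 0.0516), mast cell (0.0709), mesothelial (0.0609) and adipocyte genes (0.153). The last also failed without any 1 of day 7 replicates 2, 3 and 4 or day 14 replicates 1, 3 and 5 (adjusted p = 0.0581 to 0.0935), and mesothelial genes failed without day 7 replicate 1 (0.0551) or day 14 replicate 3 (0.239).

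**Figure D3:**
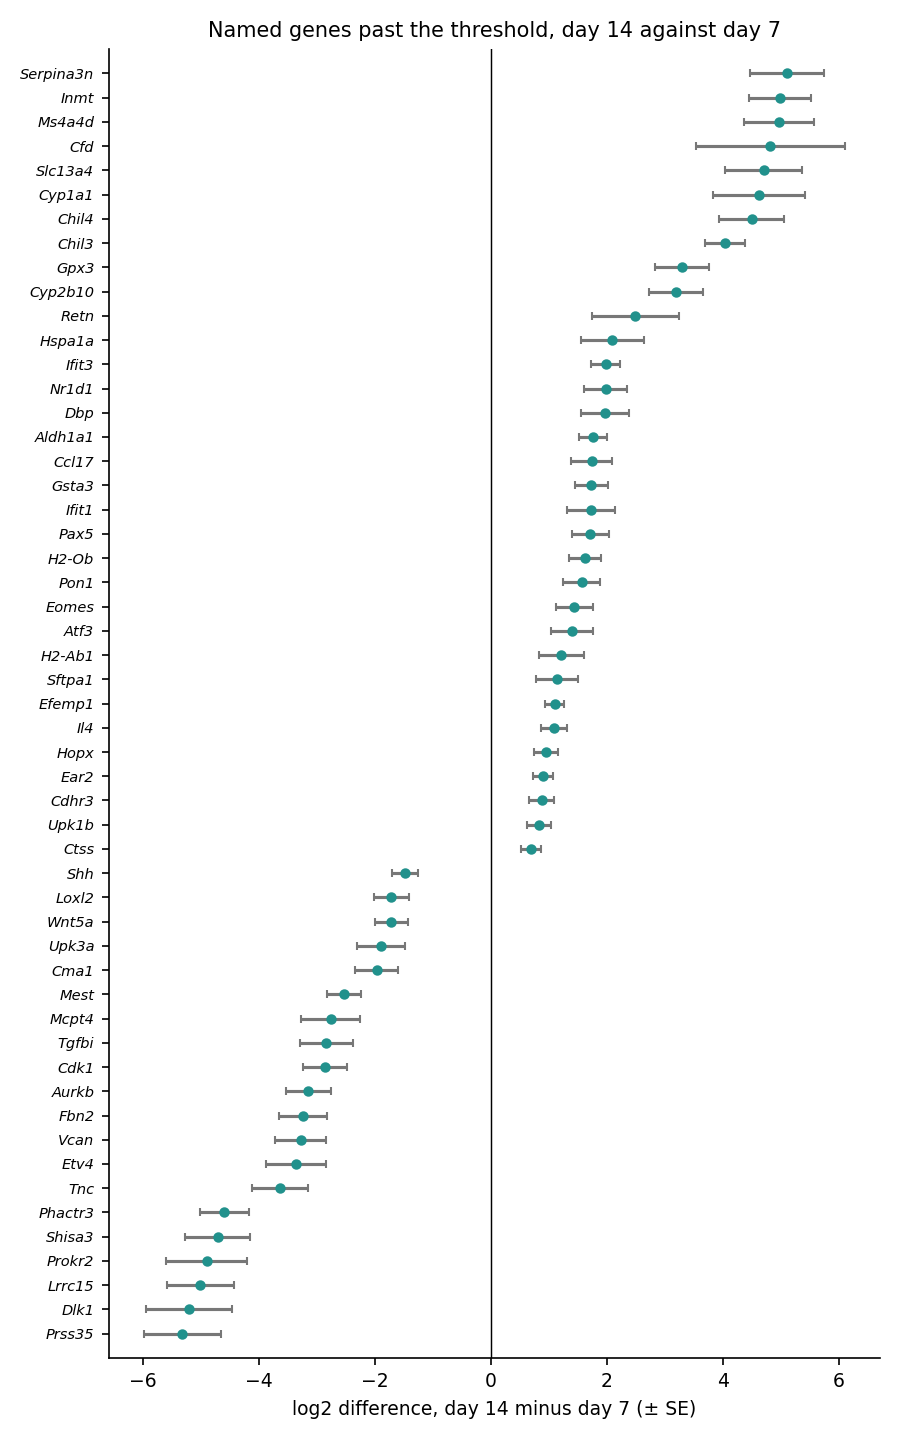
Log2 difference (day 14 minus day 7) of 53 named genes that were measured at both ages, each point with its SE (n = 5 and 5), sorted by size. The values run from -5.32 for Prss35 to 5.11 for Serpina3n.

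From day 14 to day 42 the genes named by size included lymphocyte genes that rose and red cell genes that fell. Higher at day 42 were Jchain (4.38 ± 0.81), the joining chain of secreted antibodies, Mfsd2a (3.54 ± 0.47), a lysophospholipid transporter, Gzmb (2.73 ± 0.36), a protease of cytotoxic cells, and Ifi27l2a (2.64 ± 0.41), an interferon-induced gene. Klra8 (2.63 ± 0.57), a receptor of NK cells, and Ppp2r2c (2.66 ± 0.62), a phosphatase subunit well above background on 2 of 5 day 14 arrays, were also higher. Lower were Slc4a1 (-4.11 ± 0.38), the red cell anion exchanger, Trim10 (-3.41 ± 0.40), a gene of late red cell precursors, Col10a1 (-3.53 ± 0.46), a collagen of hypertrophic cartilage, and Adamts17 (-3.03 ± 0.29), a secreted metalloprotease. Stfa1 (-3.04 ± 0.49) and Stfa3 (-3.0 ± 0.49), cysteine protease inhibitors whose probes were not tested for shared targets, fell too. These 12 genes had adjusted p = 7.23e-07 to 0.0158 (limma, n = 4 and 5), and at day 42 Col10a1 was well above background on 1 of 4 arrays and Stfa3 on 3 of 4.

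Of 19 erythroid genes 9 fell and 10 did not pass (11 lower adjusted over the list alone), adjusted p = 1.11e-19 and p = 0.000862 with estimated correlation. Kel, a blood group protein, was at least 7.45-fold lower, since it was not well above background on any day 42 array. The list median was -1.58, and -0.58 with the normexp background. Of 23 T and NK cell genes 8 rose and 15 did not pass (21 higher adjusted over the list alone, 17 without the 5 arrays), adjusted p = 2.77e-16 and p = 0.0915 with estimated correlation. Besides Gzmb, Gzma (2.63 ± 0.41), a second granzyme, and Ccl5 (2.41 ± 0.45), a chemokine, rose. Of 10 MHC class II presentation genes 1 rose and 9 did not pass (10 higher adjusted over the list alone, 7 without the 5 arrays), adjusted p = 6.7e-07 and p = 0.242 with estimated correlation. The 1 gene past the test was Ctss (0.72 ± 0.18). Of 14 B cell genes 2 rose and 12 did not pass (2 higher adjusted over the list alone), adjusted p = 0.0152 and p = 0.472 with estimated correlation. Fcer2a (1.21 ± 0.25), a low-affinity IgE receptor, and H2-Ob (1.08 ± 0.30) rose. Of 16 alveolar macrophage genes 0 passed alone and the list was called higher (6 higher adjusted over the list alone, 6 without the 5 arrays), adjusted p = 6.01e-05 and p = 0.0784 with estimated correlation. Of 22 interferon-stimulated genes 3 rose, 1 fell and 18 did not pass (7 higher and 1 lower adjusted over the list alone), adjusted p = 0.00267 and p = 0.353 with estimated correlation. Oasl1 (1.28 ± 0.32) rose and Rsad2 (-2.47 ± 0.27), the antiviral enzyme viperin, fell.

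Of 18 ciliated airway genes 5 rose and 13 did not pass (14 higher adjusted over the list alone, 12 without the 5 arrays), adjusted p = 1.58e-08 and p = 0.0784 with estimated correlation. Rsph1 (1.20 ± 0.30) and Dnali1 (1.20 ± 0.28), parts of the ciliary axoneme, were higher. Of 18 club and secretory airway genes 1 rose and 17 did not pass (5 higher adjusted over the list alone), adjusted p = 0.000178 and p = 0.327 with estimated correlation. That gene was Pon1 (1.24 ± 0.34), an esterase. Of 22 alveolar type 2 and surfactant genes 1 rose and 21 did not pass (1 higher adjusted over the list alone, 3 higher and 1 lower without the 5 arrays), adjusted p = 0.0441 and p = 0.723 with estimated correlation. It was Fasn (1.19 ± 0.33), fatty acid synthase. Of 22 cholesterol synthesis genes 3 rose and 19 did not pass (11 higher adjusted over the list alone, 13 without the 5 arrays), adjusted p = 1.58e-08 and p = 0.0734 with estimated correlation. Sqle (1.29 ± 0.28) and Msmo1 (0.93 ± 0.17), enzymes of sterol synthesis, rose. Of 22 xenobiotic and antioxidant genes 0 passed alone and the list was called higher (3 higher adjusted over the list alone, 5 without the 5 arrays), adjusted p = 0.00052 and p = 0.325 with estimated correlation. Of 9 adipocyte genes 1 rose and 8 did not pass (6 higher adjusted over the list alone, 2 without the 5 arrays), adjusted p = 0.00101 and p = 0.36 with estimated correlation. Retn (2.91 ± 0.80) was higher. Of 17 immediate early and heat shock genes 3 rose and 14 did not pass (4 higher adjusted over the list alone), adjusted p = 0.00642 and p = 0.597 with estimated correlation. Atf3 (1.39 ± 0.38) and Egr2 (0.97 ± 0.25), transcription factors of the early response, rose.

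Of 18 elastic fibre genes 1 rose, 2 fell and 15 did not pass (2 higher and 6 lower adjusted over the list alone, 2 higher and 8 lower without the 5 arrays), adjusted p = 0.00716 and p = 0.597 with estimated correlation. Eln (-2.56 ± 0.36), elastin, and Lox (-1.38 ± 0.34), lysyl oxidase, fell, while Efemp1 (0.90 ± 0.17) rose. Of 22 fibrillar collagen and stromal matrix genes 1 fell and 21 did not pass (2 lower adjusted over the list alone, 1 higher and 10 lower without the 5 arrays), adjusted p = 0.00103 and p = 0.242 with estimated correlation. It was Col5a2 (-1.44 ± 0.26), a chain of collagen V. Of 12 pericyte genes 0 passed alone and the list was called lower (0 adjusted over the list alone, 6 lower without the 5 arrays), adjusted p = 0.0292 and p = 0.103 with estimated correlation. Of 25 lung morphogen signalling genes 4 fell and 21 did not pass (8 lower adjusted over the list alone, 10 without the 5 arrays), adjusted p = 1.64e-08 and p = 0.141 with estimated correlation. Tbx5 (-0.82 ± 0.19), a T-box factor, was 1 of these. Of 18 imprinted growth genes 4 fell and 14 did not pass (1 higher and 6 lower adjusted over the list alone, 1 higher and 5 lower without the 5 arrays), adjusted p = 0.00079 and p = 0.0378 with estimated correlation. Peg3 (-2.02 ± 0.52) and Mest (-1.41 ± 0.31) fell, and the list median was -0.27, and -0.05 with median scaling. Of 18 circadian clock genes 1 rose, 4 fell and 13 did not pass (2 higher and 5 lower adjusted over the list alone), adjusted p = 0.00866 and p = 0.212 with estimated correlation. Per2 (-1.80 ± 0.29) and Per3 (-1.44 ± 0.24), repressors of the clock loop, were lower, and the list median was -0.20, -0.41 in the authors' table and 0.02 with median scaling.

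By limma 581 genes passed between day 14 and day 42 (350 higher, 231 lower), 384 by at least 2-fold. Without the 5 arrays 2088 passed, with 568 of the 581 among them, and 2191 passed without the 6 and 212 with the compared ages alone. Higher genes made up 60.2%, but 79% with median scaling, which moved the median of all genes to 0.31, and 51.4% without the 5 arrays. With a slide block 533 genes passed, and 99.7%, 100% and 99.3% of the 581 kept their direction within slides. Counts fell to 377 without day 14 replicate 4, 368 without day 42 replicate 1 and 338 without day 42 replicate 2. All 19 lists kept their call with the block, but medians ran against it within slide 3 for elastic fibre (0.23), pericyte (0.66), adipocyte (-0.17) and circadian clock genes (0.07). The same held for alveolar type 2 and surfactant genes on slide 1 (-0.22), and for B cell (-0.04) and immediate early and heat shock genes (-0.01) on slide 2. The alveolar type 2 and surfactant call was lost without the 5 arrays (adjusted p = 0.174) and without any 1 of day 14 replicate 5 (0.108) and day 42 replicates 2, 3 and 4 (0.0804, 0.087 and 0.181). Without day 14 replicate 5, calls also ended for elastic fibre (adjusted p = 0.0634), pericyte (0.0829), B cell (0.219), interferon-stimulated (0.08) and immediate early and heat shock genes (0.178). Single day 42 arrays ended the call for pericyte (0.0634 without replicate 2, 0.0613 without replicate 3), B cell (0.308 without replicate 1), adipocyte (0.0962 without replicate 1) and immediate early and heat shock genes (0.208 without replicate 2).

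Across the whole course, day 42 against day 1, the largest rises were those of Cfd (10.81 ± 1.36), Bpifa1 (8.15 ± 1.74), a secreted airway protein, Mmp3 (7.33 ± 0.49), a matrix metalloprotease, Inmt (7.31 ± 0.57), Adipoq (7.19 ± 1.39), the adipokine adiponectin, and Lrat (6.64 ± 0.75), which esterifies retinol. The largest falls were those of Dlk1 (-7.77 ± 0.79), Tnni1 (-6.12 ± 0.95), a slow muscle troponin, Trim67 (-5.87 ± 0.76), Stfa3 (-5.85 ± 0.49), Stfa1 (-5.84 ± 0.49) and Lrrc15 (-5.67 ± 0.62). Adjusted p for these 12 was 1.1e-09 to 0.00102 (limma, n = 4 and 5). At day 1 Cfd and Mmp3 were well above background on 1 of 5 arrays, Adipoq on 2 of 5, and Bpifa1 and Lrat on 3 of 5, and at day 42 Tnni1 was on 2 of 4.

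Of 42 cell cycle genes 41 fell and 1 did not pass (41 lower adjusted over the list alone), adjusted p = 3.42e-31 and p = 0.0323 with estimated correlation. Aurkb was at least 13-fold lower, and Cdk1 (-4.07 ± 0.40) fell. Its median difference was -2.91 (-2.91 with a slide block and -2.91, -3.20 and -2.23 within slides). Of 18 imprinted growth genes 13 fell and 5 did not pass (13 lower adjusted over the list alone, 2 higher and 14 lower without the 5 arrays), adjusted p = 9.17e-09 and p = 0.000862 with estimated correlation. Mest (-4.87 ± 0.31) fell with Dlk1, and the median was -1.80. Of 25 lung morphogen signalling genes 17 fell and 8 did not pass (18 lower adjusted over the list alone, 1 higher and 19 lower without the 5 arrays), adjusted p = 1.47e-08 and p = 0.14 with estimated correlation. Sox9 (-2.76 ± 0.29), a factor of distal lung progenitors, and Gli1 (-2.27 ± 0.26), a Hedgehog target, fell. Of 19 erythroid genes 13 fell and 6 did not pass (14 lower adjusted over the list alone), adjusted p = 2.19e-07 and p = 0.0378 with estimated correlation. Kel was at least 12.7-fold lower and Slc4a1 (-4.46 ± 0.38) fell, with a list median of -1.54 (-0.91 with the normexp background). Of 8 mast cell genes 5 fell and 3 did not pass (1 higher and 5 lower adjusted over the list alone, 2 higher and 5 lower without the 5 arrays), adjusted p = 0.0183 and p = 0.242 with estimated correlation. Mcpt4 (-4.23 ± 0.54) and Cpa3 (-2.94 ± 0.57), mast cell proteases, fell.

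Of 18 elastic fibre genes 1 rose, 11 fell and 6 did not pass (2 higher and 11 lower adjusted over the list alone, 2 higher and 14 lower without the 5 arrays), adjusted p = 0.000359 and p = 0.485 with estimated correlation. Fbn2 (-4.87 ± 0.43) and Loxl2 (-2.96 ± 0.32) fell and Efemp1 (2.22 ± 0.17) rose, and the list median was -1.39 (-1.37 with a slide block and -1.96, -1.60 and 0.22 within slides), where the only day 42 array on slide 3 is replicate 4. Of 22 fibrillar collagen and stromal matrix genes 2 rose, 12 fell and 8 did not pass (3 higher and 13 lower adjusted over the list alone), adjusted p = 0.000816 and p = 0.242 with estimated correlation. Tnc (-4.76 ± 0.52), well above background on 1 of 4 day 42 arrays, and Col5a1 (-2.14 ± 0.32), a collagen V chain, fell. Of 19 smooth muscle and myofibroblast genes 3 rose, 8 fell and 8 did not pass (3 higher and 10 lower adjusted over the list alone), adjusted p = 0.0175 and p = 0.377 with estimated correlation. Tgfbi (-3.12 ± 0.48) and Myocd (-2.60 ± 0.32), the coactivator of smooth muscle genes, fell. Of 19 alveolar type 1 genes 4 rose and 15 did not pass (4 higher adjusted over the list alone, 10 higher and 1 lower without the 5 arrays), adjusted p = 0.0086 and p = 0.324 with estimated correlation. Cyp2b10 (4.78 ± 0.48) and Clic5 (1.84 ± 0.38), a chloride channel protein, rose, while the median within slide 1 was -0.32. Of 18 ciliated airway genes 10 rose and 8 did not pass (11 higher adjusted over the list alone), adjusted p = 2.53e-06 and p = 0.14 with estimated correlation. Cdhr3 (2.04 ± 0.23) and Dnah5 (1.94 ± 0.37), a dynein of cilia, rose. Of 18 club and secretory airway genes 11 rose, 1 fell and 6 did not pass (13 higher and 1 lower adjusted over the list alone), adjusted p = 1.1e-05 and p = 0.242 with estimated correlation. Besides Bpifa1, Muc5b (4.23 ± 1.21), an airway mucin, rose, and it did not pass without the 5 arrays. Of 22 xenobiotic and antioxidant genes 15 rose and 7 did not pass (15 higher adjusted over the list alone), adjusted p = 2.42e-08 and p = 0.0945 with estimated correlation. Cyp2e1 (3.39 ± 0.54) and Sod3 (3.29 ± 0.41), an extracellular superoxide dismutase, rose.

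Of 23 T and NK cell genes 20 rose and 3 did not pass (21 higher adjusted over the list alone), adjusted p = 8.2e-18 and p = 0.0805 with estimated correlation. Il7r (3.97 ± 0.60), the interleukin 7 receptor, and Gzma (3.50 ± 0.41) rose, and Ncr1, an NK cell receptor, was at least 5.65-fold higher. Of 14 B cell genes 13 rose and 1 did not pass (13 higher adjusted over the list alone), adjusted p = 8.15e-09 and p = 0.0577 with estimated correlation. H2-Ob (3.88 ± 0.30) rose, and Pax5 was at least 3.1-fold higher. Of 10 MHC class II presentation genes all rose (10 higher adjusted over the list alone), adjusted p = 1.29e-07 and p = 0.23 with estimated correlation. H2-Ab1 (2.45 ± 0.41) and H2-Aa (2.38 ± 0.40), the chains of one class II molecule, rose. Of 16 alveolar macrophage genes 12 rose and 4 did not pass (15 higher adjusted over the list alone), adjusted p = 7.71e-09 and p = 0.0267 with estimated correlation. Chil3 (5.78 ± 0.36) and Fabp1 (5.30 ± 0.63), a fatty acid binding protein, rose, with a list median of 1.17. Of 22 interferon-stimulated genes 19 rose, 1 fell and 2 did not pass (19 higher and 1 lower adjusted over the list alone), adjusted p = 1.1e-10 and p = 0.038 with estimated correlation. Ifit3 (3.69 ± 0.27) and Ifit1 (2.98 ± 0.45) rose, and the list median was 1.70. Of 16 type 2 immune response genes 6 rose and 10 did not pass (6 higher adjusted over the list alone), adjusted p = 0.000918 and p = 0.184 with estimated correlation. Ccl17 (2.88 ± 0.38) and Il33 (1.41 ± 0.25), an alarm cytokine of epithelium, rose. Of 17 immediate early and heat shock genes 9 rose and 8 did not pass (10 higher adjusted over the list alone), adjusted p = 0.000153 and p = 0.472 with estimated correlation. Hspa1a (3.19 ± 0.58) and Fos (1.88 ± 0.49) rose.

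Of 9 adipocyte genes 6 rose and 3 did not pass (6 higher adjusted over the list alone), adjusted p = 0.000265 and p = 0.295 with estimated correlation. Cfd, Adipoq and Retn (6.36 ± 0.80) rose. Of 9 mesothelial genes 4 rose, 1 fell and 4 did not pass (4 higher and 1 lower adjusted over the list alone), adjusted p = 0.0441 and p = 0.54 with estimated correlation. Upk1b (1.21 ± 0.23) rose, while Msln (-1.21 ± 0.36), mesothelin, fell. The mesothelial and mast cell calls were lost without the 5 arrays (adjusted p = 0.0884 and 0.133). Without day 42 replicate 4 the mast cell list had adjusted p = 0.0573, and the mesothelial list had 0.0707 and 0.0746 without day 1 replicates 3 and 5 and 0.0962 and 0.0541 without day 42 replicates 1 and 2.

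By limma 4184 genes passed between day 1 and day 42 (2058 higher, 2126 lower), 2804 by at least 2-fold. Without the 5 arrays 7341 passed, with 4069 of the 4184 among them in the same direction, and 7613 passed without the 6 and 2124 with the compared ages alone. With a slide block 3964 genes passed, and 99.4%, 100% and 78.8% of the 4184 kept their direction within slides. All 21 lists kept their call with the block, and 19 the sign of their median within every slide, the others being alveolar type 1 and elastic fibre genes.

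**Figure D4:**
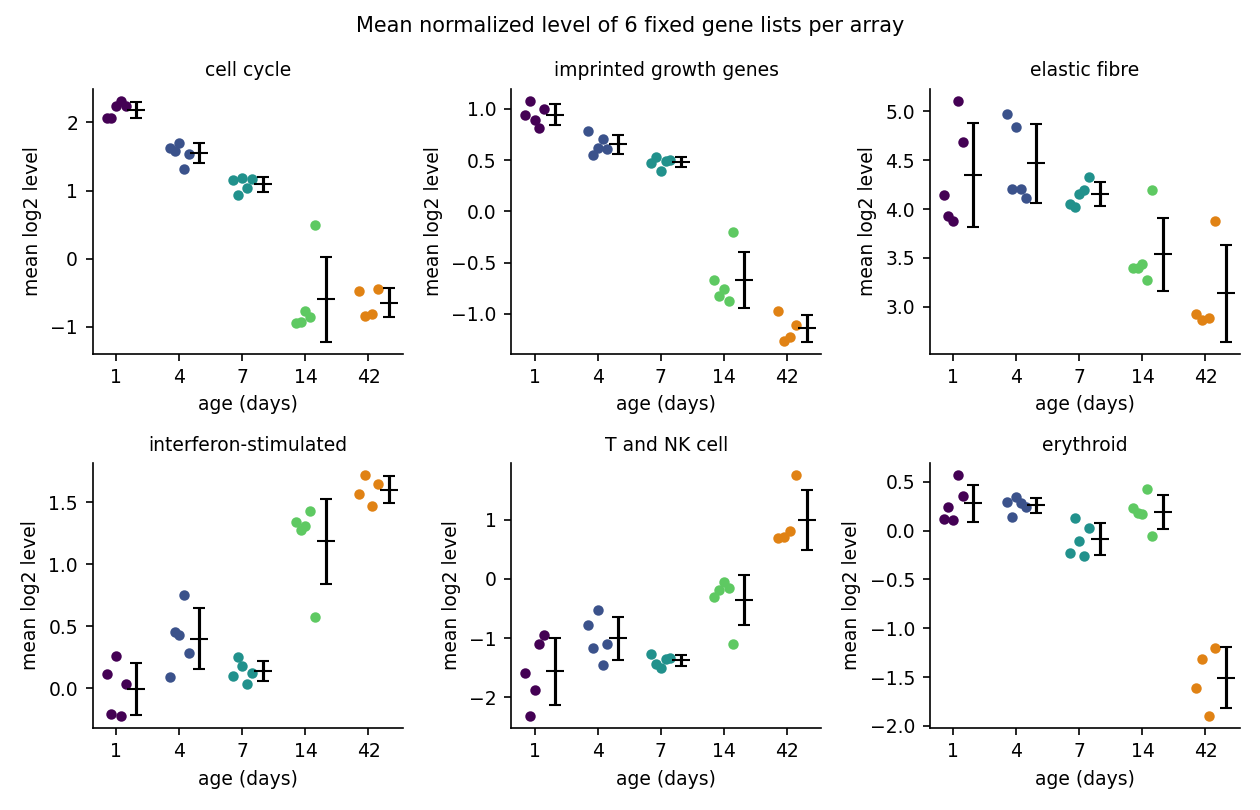
Mean normalized log2 level of 6 fixed gene lists on each array by age in days, with the mean ± SD of each age beside the points (n = 5, and 4 at day 42). The cell cycle list falls from 2.19 at day 1 to -0.65 at day 42.

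By the fitted means, some genes stood at least 2-fold higher or lower at an intermediate age than at both days 1 and 42, and bounds for genes at background can be smaller. Highest at day 7 were 8 genes, 6 without the sex-linked Eif2s3y and Uty. All day 7 arrays had Ddx3y and most day 42 arrays Xist, so the day 7 counts were not separated from sex. Eif2s3y changed by 4.03 ± 1.03 from day 1 and then -3.70 ± 1.1 to day 42. Uty was at least 2.38 and 2.89-fold higher than at days 1 and 42. Prokr2 rose by 3.15 ± 0.71 from day 1 and was then at least 12.1-fold lower at day 42. Odf4 rose by 1.59 ± 0.39 from day 1, a change of -0.02 with the normexp background, and was well above background on 1 of 5 day 1 arrays, where Prokr2 was on 3. Lowest at day 7 were 27 genes, among them Cyp1a1 (-3.66 ± 0.80 against day 1, then 7.23 ± 0.85 to day 42). Slc1a2, a glutamate transporter, and Pdcd1, an inhibitory receptor of T cells, were at least 2.05 and 2.84-fold lower at day 7 than at day 1, since neither was well above background on any day 7 array.

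Highest at day 14 were 15 genes. Ptx4, a pentraxin, rose by 2.54 ± 0.43 from day 1 and was at least 5.48-fold lower at day 42. Rag1, the recombinase of lymphocyte precursors, rose by 2.20 ± 0.74 and was at least 2.91-fold lower. At day 1 Ptx4 was well above background on 1 of 5 arrays and Rag1 on 2. Col10a1 changed by 1.68 ± 0.44 to day 14 and -3.53 ± 0.46 to day 42. Lowest at day 14 were 9 genes, among them Cma1 (-4.13 ± 0.37, then 1.48 ± 0.40) and Sqle (-1.39 ± 0.27, then 1.29 ± 0.28).

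At day 4 there were 0 such genes in either direction by limma, although 814 genes had an unadjusted p under 0.05 between days 1 and 4. Both contrasts share the intermediate age, and the simulated mean with no effect was 0 for all 6 counts. Shuffled age labels reached 1441 genes highest and 1338 lowest at day 14, so that 0 does not exclude chance there. Independent lists would overlap in 0.2397, 3.566 and 10.66 genes highest and 0.1662, 24.99 and 20.14 genes lowest at days 4, 7 and 14. With separate arrays of the shared age for each contrast, the counts were 0, 0 and 8 highest and 0, 0 and 5 lowest. Without the 5 arrays they were 1, 6 and 36 highest and 0, 11 and 7 lowest. Adding the Xist covariate to that gave 3 highest and 3 lowest at day 7. Without the 6 arrays they were 9, 22 and 61 highest and 1, 17 and 21 lowest. With a slide block they were 0, 6 and 15 highest and 0, 34 and 10 lowest. Leaving out day 14 replicate 5 gave 9, 25 and 27 genes highest at days 4, 7 and 14. Lowest at day 14 were then 22, or 5 when only day 42 replicate 4 was left out. The 8 genes highest at day 7 became 19 without day 1 replicate 3, 14 without day 42 replicate 4, and 1 to 5 without any 1 of day 1 replicates 4 and 5, day 7 replicates 1, 2, 3 and 4, and day 42 replicate 2. The 27 genes lowest at day 7 became 45 to 67 without any 1 of day 1 replicates 2 and 3 and day 7 replicate 5. Without any 1 of the arrays that gave 1 to 5 above, they became 3 to 15.

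The 6 remaining lists passed in no comparison. From day 1 to day 42 the members that rose and fell were, for Car4-positive capillary genes 1 and 1 of 12 (adjusted p = 0.654), platelet and megakaryocyte genes 1 and 2 of 10 (0.278), neuroendocrine and nerve genes 1 and 1 of 14 (0.998), skeletal muscle genes 0 and 2 of 8 (0.312), thymocyte genes 2 and 1 of 8 (0.439) and cartilage genes 1 and 3 of 9 (0.0968).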

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

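The tests of the 5 arrays and those of a wrong age or the slide for day 14 replicate 5 were chosen after the result was seen, while the test of mixed RNA and the splits of the samples were chosen before.

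Among the 4 or 5 arrays of each age, a value was picked out when its gap to the nearest other array, divided by the range of the age, passed Dixon's limit for that number of arrays. Chance picks out about 1 in 20 groups, and 112 of 805 groups were picked out, 65 of them by day 14 replicate 5 and 19 by day 42 replicate 4. Over all 201 genes of the naming rule 158 of 1195 groups were. The ratio is in parentheses in each case. Day 14 replicate 5 stood above the rest of its age for the lists cell cycle (0.8788), elastic fibre (0.8256), fibrillar collagen and stromal matrix (0.8943) and smooth muscle and myofibroblast (0.8063). For single genes it stood above for Prss35 (0.8057), Lrrc15 (0.9651), Prokr2 (0.9487), Shisa3 (0.7212), Phactr3 (0.8739), Cdk1 (0.9212), Upk3a (0.785), Fbn2 (0.8977), Loxl2 (0.8794), Vcan (0.8285), Tgfbi (0.9943), Wnt5a (0.868), Mest (0.8025), Etv4 (0.9882) and Shh (0.7361). It also did so for Stfa1 (0.8395), Stfa3 (0.9073), Trim67 (0.8975), Col5a1 (0.8492) and Myocd (0.7971). Day 14 replicate 5 stood below the rest of its age for the lists alveolar type 1 (0.8709), alveolar macrophage (0.7624), B cell (0.8598), T and NK cell (0.7621), MHC class II presentation (0.8513), interferon-stimulated (0.8218), xenobiotic and antioxidant (0.8219) and immediate early and heat shock (0.7313). For single genes it stood below for Cd209a (0.8919), Serpina3n (0.8203), Inmt (0.9258), Ms4a4d (0.9684), Slc13a4 (0.8808), Cyp2b10 (0.8731), Sftpa1 (0.7269), Aldh1a1 (0.7846), Gsta3 (0.8655), Pax5 (0.8551), Eomes (0.7659), H2-Ab1 (0.9033), Ifit3 (0.8839), Gpx3 (0.7441) and Cyp1a1 (0.7185). It also did so for Nr1d1 (0.8085), Dbp (0.7217), Hspa1a (0.7511), Gzmb (0.7553), Klra8 (0.8009), Trim10 (0.7705), Fcer2a (0.7268), Rsad2 (0.7914), Oasl1 (0.7513), Per2 (0.7714), Per3 (0.8955), Mmp3 (0.8897), Lrat (0.8867), Fabp1 (0.8242) and Ifit1 (0.7187). The same held for Sod3 (0.8142), Slc1a2 (0.7195) and Ptx4 (0.765). Day 42 replicate 4 stood above the rest of its age for the lists elastic fibre (0.9408), Car4-positive capillary (0.8822), T and NK cell (0.8766) and xenobiotic and antioxidant (0.8366). For single genes it stood above for Prkcq (0.9657), Serpina3n (0.8294), H2-Ab1 (0.8961), Gpx3 (0.8853), Upk1b (0.9531), Dnali1 (0.8545), Mmp3 (0.9422) and H2-Aa (0.8706). Day 42 replicate 4 stood below the rest of its age for the list sex-linked (0.9355), and in its share of spots over background (0.8426). For single genes it stood below for Xist (0.9202), Lox (0.8455), Lrat (0.8468), Dnah5 (0.8847) and Il7r (0.948). Day 7 replicate 5 stood above for the Car4-positive capillary list (0.8656), the type 2 immune response list (0.7142), the xenobiotic and antioxidant list (0.7384), Sftpa1 (0.8349), Upk3a (0.7857), Slc4a1 (0.7244) and Rsad2 (0.7177), and below for Ddx3y (0.7552) and Uty (0.8414); day 14 replicate 3 stood above for the thymocyte list (0.9318), Tbx5 (0.7237), Pdcd1 (0.7771) and its share of spots over background (0.8272). Day 7 replicate 4 stood above for Vsnl1 (0.7571) and Tbx5 (0.8191), and below for Dnah5 (0.7518); day 1 replicate 2 stood above for the cardiac muscle list (0.7283) and Tnni1 (0.7302). Day 4 replicate 4 stood above for Chil3 (0.7162) and Il33 (0.7624); day 4 replicate 2 stood above for Ddx3y (0.8332) and Eif2s3y (0.7462). Day 42 replicate 1 stood above for the lipofibroblast list (0.9009); day 7 replicate 3 stood below for Pde4b (0.7358). Day 7 replicate 1 stood below for Fbn2 (0.7113); day 42 replicate 3 stood above for Shh (0.8703). Day 4 replicate 1 stood below for Col10a1 (0.7542); day 7 replicate 2 stood above for Fabp1 (0.8507). Probes without a gene name here that were well above background on all 24 arrays numbered 8262.

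The 5 arrays that stood apart were also the dimmest (75th percentile at most 979.3, others at least 995.5), and their deviations from the other arrays of their age correlated across genes with a mean of 0.9. The slide and the age of the animals are argued against, since the 5 arrays lay on 3 slides and 3 ages held both kinds of array. Brightness that changed alike for all genes is argued against by the mean correlation of 0.877 that remained after quantile normalization, where other arrays had 0.00137 on average and 0.378 at most. Loss of some transcripts before hybridization may account for the pattern: on 5 of the 5 arrays neither Xist nor Ddx3y was well above background, against 0 of 19 others, although at least 92.2% of 1550 genes near the usual Xist level were. What could have removed them stays open, and no biological explanation was tested.

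Day 14 replicate 5 lay between day 7 and day 14, at 0.276 on a scale where the day 7 mean is 0 and the mean of the other day 14 arrays is 1, over 1534 genes. A plain day 7 sample under the wrong label is argued against, since day 7 arrays reached at most 0.0119, and the slide is argued against by the other day 14 array on it, at 0.995. Day 14 RNA mixed with day 7 RNA cannot be told apart from other causes: genes that rose gave a day 14 share of 0.198 and genes that fell 0.406, a difference of -0.208 that would exclude mixing on its own, but another array differed by 0.273. That spread was brought in after the difference was seen. Slower development of that animal could also give such a position and was not tested.

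In other splits of the arrays of a pair of ages, 1 of 100 splits, the real one included, gave as many genes between days 7 and 14 (1796 real, 995 the highest other) and days 14 and 42 (581, 142). That is the fewest that 100 splits can give. It argues against chance there, but among many uncorrected tests it does not exclude it. Between days 4 and 7, 1 of 100 did (1, 0), but that count of 1 was 0 in other settings, so nothing is concluded from it. Between days 1 and 4, 5 of 100 splits did (9, 11050), and between days 1 and 42, 13 of 100 (4184, 10692), so chance was not excluded by this count. The splits with most genes put all 4 and all 3 of the apart-standing arrays of those ages on one side, which points to a structure of the samples. For gene lists, 4, 69, 24, 14 and 15 of 100 splits gave as many in the 5 comparisons (16, 6, 22, 19 and 21). The highest other counts were 19, 14, 28, 21 and 25, and the median ones 8, 8, 16, 12 and 13. Chance was not excluded, since the 4 is 1 of many uncorrected tests. With the 24 ages in other orders, 3 of 100 gave as many genes that differ between any ages (4995, 9733). For genes highest at day 7, 1 of 100 orders did (8, 0), for those lowest 1 of 100 (27, 0), and for day 14, 2 of 100 both for highest (15, 1441) and for lowest (9, 1338). At day 4, where both counts were 0 by limma, 100 of 100 did (0, 0), and 814 genes had an unadjusted p under 0.05 against day 1.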

How the results depend on the processing

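All settings without 5 arrays, 6 arrays or sex-linked genes were chosen after seeing the data. Every count of genes (by limma) or lists that moved by over 1.5 times follows by setting, with the ages in parentheses, and the cause was not tested unless the setting uses fewer arrays. Median spot signals with the normexp background gave 3 (days 1 and 4) and 3 (days 4 and 7), and 7 (lowest day 7), 4 (highest day 14) and 3 (lowest day 14). Quantile normalization gave 32, 6, 2855 and 975 in the first 4 comparisons, and 3 gene lists (days 4 and 7). It gave 2 (highest day 4), 20 (highest day 7) and 21 (lowest day 14). Median scaling gave 4 (days 1 and 4) and 0 (days 4 and 7), and 3 (highest day 7) and 6 (lowest day 7). The authors' table gave 99, 20, 3562 and 1524 in the first 4 comparisons, and 5 (highest day 4), 26 (highest day 7) and 21 (lowest day 14). No filter on dim probes gave 1 (highest day 4) and 4 (highest day 7). A filter that asks for all 24 arrays above background gave 4 (days 4 and 7), and 3 (highest day 7) and 7 (highest day 14), and 2 (days 4 and 7) for gene lists. The mean of a gene's probes gave 1 (highest day 4). Each probe tested on its own gave 16 (highest day 7). The Xist level as a covariate gave 22 (days 1 and 4), 9016 (days 4 and 7), 1025 (days 14 and 42) and 11569 (any ages), and 2 (highest day 4), 1260 (highest day 7), 771 (lowest day 7) and 24 (lowest day 14). Array weights gave 489, 5160, 9595, 4892 and 8256 in the 5 comparisons and 12897 for any ages. At days 4, 7 and 14 they gave 13, 34 and 57 highest and 7, 52 and 43 lowest. A variance trend gave 3 (days 4 and 7). The arrays of the compared ages alone gave 0, 0, 4856, 212 and 2124 in the 5 comparisons. Leaving out the 5 arrays gave 8, 6048, 2088 and 7341 in the last 4 comparisons, 8488 for any ages, and 1 (highest day 4), 11 (lowest day 7) and 36 (highest day 14). Leaving out the 6 arrays gave 254, 31, 6995, 2191 and 7613 in the 5 comparisons and 8996 for any ages. At days 4, 7 and 14 it gave 9, 22 and 61 highest and 1, 17 and 21 lowest. The Xist covariate without the 5 arrays gave 17, 5, 4277, 1682 and 7296 in the 5 comparisons and 8154 for any ages. It gave 1, 3 and 39 highest at days 4, 7 and 14, and 3 lowest at day 7. An estimated correlation gave 4, 1, 4, 2 and 5 gene lists in the 5 comparisons. The fry test gave 7 (days 1 and 4) for gene lists. Where the count was 0, 1231 genes between days 4 and 7 had an unadjusted p under 0.05 with median scaling, and with the compared ages alone 496 between days 1 and 4 and 4185 between days 4 and 7.

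Omitting each array in turn gave 4 to 44, 1 to 14, 1310 to 2298, 338 to 841 and 3391 to 5772 genes per comparison. For any ages it gave 4349 to 6285. Genes highest at days 4, 7 and 14 ranged over 0 to 9, 1 to 25 and 10 to 27, and those lowest over 0 to 0, 3 to 67 and 5 to 22. Lists called ranged over 11 to 18, 4 to 8, 20 to 23, 16 to 21 and 20 to 22 in the same order.

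Directions turned in 8 cases, and the cause was not tested. With the normexp background Odf4 changed by -0.0246 between days 1 and 7, and with the Xist covariate without the 5 arrays Eif2s3y changed by 0.02276 between days 7 and 42. Between days 1 and 4 the cardiac muscle list turned without day 1 replicate 2 (adjusted p = 0.479, range over single arrays 8.34e-09 to 0.479), and the platelet and megakaryocyte list, not called with all arrays, turned without day 1 replicate 4 (0.0258, range 0.0258 to 0.999) and without the 5 arrays (0.0459). Between days 14 and 42 the cell cycle list, not called with all arrays, turned without day 14 replicate 5 (0.0225, range 0.0225 to 0.751) and without the 6 arrays (0.00243). Between days 4 and 7 the immediate early and heat shock list turned with the Xist covariate without the 5 arrays (0.836). Over all alternatives, 7310 of 7730 values of single lists kept their direction and their side of the threshold, 253 lost a call and 161 gained one. Of 11760 values of named genes, 11117 kept both and 641 lost a call.

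With a replicate block the counts were 8, 1, 1666, 488 and 3754 genes in the 5 comparisons, 4518 for any ages, and 5 genes highest at day 7 in place of 8. The numbers did not pair the samples: deviations of arrays with the same number correlated between -0.849 and 0.879, and 4 of 24 arrays correlated best with their own number. Between slides the mean correlation was 0.01, and 0.0229 within a slide.

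Signal over background limited the folds: in 2, 0, 110, 41 and 258 of the genes called in the 5 comparisons, 1 of the ages had 0 arrays well above background.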

Other observations

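Genes that share the letters of their symbol were grouped after the data were examined, which gave 109 families of at least 15 genes and 545 tests by camera. In the 5 comparisons 7, 5, 15, 11 and 18 families passed, 0 of them with an estimated correlation, and 6, 10, 21, 12 and 20 passed without the 5 arrays. From day 7 to day 14, 20 of 88 genes with Cd symbols, cell surface antigens, rose and 2 fell (median 0.65, adjusted p = 4.67e-08, and p = 0.434 with estimated correlation), and from day 1 to day 42 47 rose and 5 fell (adjusted p = 1.87e-10, and p = 0.314 with estimated correlation). Of 61 interleukin and receptor genes (Il) 16 rose and 1 fell from day 7 to day 14 (adjusted p = 4.95e-07, and p = 0.314 with estimated correlation), and 32 rose and 1 fell from day 1 to day 42 (adjusted p = 1.62e-07, and p = 0.314 with estimated correlation). Collagen genes (Col) fell from day 14 to day 42 in 6 of 38 cases (adjusted p = 3.1e-08, and p = 0.314 with estimated correlation), and from day 1 to day 42 21 fell and 4 rose (median -1.17, adjusted p = 0.000178, and p = 0.696 with estimated correlation). In each case the median of the family kept its sign with the normexp background, quantile normalization, median scaling and the authors' table.

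Protocadherin beta genes (Pcdhb), cell adhesion molecules, shifted up as a group from day 1 to day 4 (median 0.38 over 20 genes, adjusted p = 6.12e-11, and p = 0.304 with estimated correlation). Zinc finger genes (Zfp) did so from day 4 to day 7 (median 0.39 over 344 genes, adjusted p = 4.81e-15, and p = 0.308 with estimated correlation), and both medians kept their sign in the same way (0.17 for Pcdhb with the normexp background, 0.59 for Zfp in the authors' table). Zfp genes also lay low on the 5 arrays that stand apart, with a median deviation of -0.92 from the other arrays of their ages, against 0.91 for ribosomal Rpl and 0.87 for mitochondrial ribosomal Mrpl genes. Day 4 replicates 1 and 3 are among the 5 and no day 7 array is, so the Zfp rise was not separated from them.

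Of 15653 probes tested without a gene name, 869, 314 and 2420 passed limma's test from day 7 to 14, 14 to 42 and 1 to 42, and 2966 differed between any ages. Day 14 replicate 3 was the only array with both Xist and Ddx3y well above background, and it had the highest share of spots well above background (79.7%).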
